A study of Homo sapiens with 12 samples.

How the data were processed

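RNA was measured in 12 libraries of HPAF-II, a human pancreatic adenocarcinoma cell line carrying a mutated RNF43 gene. The cells had been treated in culture with ETC-159, a small molecule that inhibits the acyltransferase PORCN, or with vehicle, for 24 h or 48 h. Each of the 4 groups held 3 libraries, prepared with a stranded kit that enriches polyadenylated RNA, per the labels' protocols. The dose, and whether the replicates of a group came from separate cultures, are not given in the sources used here. The p-values therefore measure only the spread between these samples, which can be technical. Libraries are written as V for vehicle or E for ETC-159, then the time and the replicate, so that E24r2 is ETC-159 at 24 h, replicate 2.

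The authors deposited 1 table per library with an expected count, a TPM value and an effective length for each of 60499 gene IDs. Cutadapt, STAR, RSEM and the genome build hg38 are named, without versions, in the submitters' processing notes. The expected counts are RSEM's estimates of reads per gene, per the file headers, and were deposited without normalization. Between 4.43 and 4.82% of the 60499 gene IDs, those at 0 included, had a value that was not whole in a library. The deposited TPM values summed to the fixed total that defines the unit in each library, within rounding. RSEM's effective length, in bases, weighs the isoforms of a gene by their estimated abundance, per the file headers. The gene annotation release and the strand setting of the counting are not given in the sources used here. Antisense and overlapping genes are for that reason called uncertain, as are genes with near-identical copies and readthrough genes, among which RSEM divides reads by estimation. A further table with 196 columns of per-sample values, none of which carried the name of this line, the drug or the vehicle (0 of 196), was not used here.

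Symbols and coordinates came from GENCODE release 44 on hg38, matched by gene ID. A symbol was found for 56321 IDs and none for 4178. At least 1 library had a count above 0 for 26475 IDs. Total expected counts ranged from 21020122 to 27766813 per library. No pair of replicates was identical, and counts of replicate pairs differed by more than sampling noise, with chi-square per degree of freedom between 2.72 and 21.0.

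Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr by group, which left 14808, and libraries were scaled by TMM. All 12 libraries entered 1 quasi-likelihood fit with robust estimation and 1 coefficient per group, with 8 residual degrees of freedom, a median prior of 12.8 degrees of freedom and a common biological coefficient of variation of 4.95%. Genes were tested for ETC-159 against vehicle at 24 h and at 48 h, for the difference between these responses (48 h minus 24 h), and for vehicle at 48 h against vehicle at 24 h. The p-values were two-sided and adjusted by the Benjamini-Hochberg method over genes within a comparison, and an adjusted p under 0.05 was called. Log2 fold changes are given ± SE, the SE being the fold change divided by the square root of the F statistic, and levels as TMM-scaled CPM ± SD, with n = 3 libraries per group throughout.

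In all, 28 gene lists with 764 entries were written from textbook knowledge. Of these entries 20 were matched by an older symbol and 1 stayed unmatched. Each list was tested with camera in limma 3.58.1, which compares its members with all other genes at a preset correlation of 0.01, and p-values were adjusted over lists within a comparison. Every list had at least 5 tested members. Camera with a correlation estimated from the data, and fry, were run as alternatives. With the estimated correlation 4 lists were called at each time: Wnt targets, the basal-like subtype list, mucins and YAP/TEAD targets. Neither the difference between times nor the vehicle time course then had a called list (0 lists each by camera with an estimated correlation, 5 and 2 at an unadjusted p under 0.05, 5 and 21 by fry).

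The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Named were PORCN and 9 Wnt pathway genes, then at each time the 8 highest and the 8 lowest fold changes among called genes with a symbol, a CPM of at least 2 in the higher group and the same sign in all 9 pairs of libraries. For the difference between times and for vehicle the 5 highest and 5 lowest were named by that rule, without the pair criterion for the difference. From each list up to 3 called members with the smallest p at 48 h were named, filled from 24 h where fewer passed. Some genes that this rule takes are not reported here.

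The functions were tested on counts simulated from these libraries' means, sizes and dispersions, with 50 genes changed at each of 4 fold sizes. At 24 h 42%, 72% and 88% of genes changed 1.2-, 1.5- and 2-fold were recovered, with 6 false calls among 14612. At 48 h the shares were 44%, 76% and 86%, with 11 among 14610. For the difference they were 6%, 70% and 80%, with 12 among 14614. For vehicle they were 34%, 70% and 80%, with 14 among 14615. Real comparisons called 7.27 to 54.7%, more than were changed here, so these figures do not carry over. Camera recovered a list shifted 1.15-fold at 48 h and called 0 of 26 other lists. With genes simulated independently, this leaves correlated lists untested.

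Alternatives were RLE, upper-quartile and library-size scaling, no filter or a CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), unrounded counts, offsets from the effective lengths, fits of only the groups compared, a minimum fold of 1.2 (glmTreat), the replicate number as a block, and omission of each library in turn. After the data were seen 2 more were added, omission of V48r3 and E48r2, the libraries with the highest mitochondrial share of counts at 48 h, and removal of the mitochondrially encoded genes before scaling. No scaling moved the median of all genes by more than 0.0658 on the log2 scale. Tables and figures were made with Python 3.11.15.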

Results

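HPAF-II cells carry a mutation in RNF43, which encodes a ubiquitin ligase that removes Frizzled receptors from the cell surface, and ETC-159 blocks PORCN, the acyltransferase that every secreted Wnt needs. The design compares the transcriptome of this line after 24 h and 48 h of the drug with that of cells given vehicle for as long. The 3 libraries of each group held 23225236 to 27766813 expected counts for vehicle at 24 h, 23535470 to 24424332 for ETC-159 at 24 h, 22891131 to 25130182 for vehicle at 48 h and 21020122 to 25137720 for ETC-159 at 48 h. Mitochondrially encoded transcripts took 2.82 to 3.40% of counts in vehicle and 3.20 to 3.30% in ETC-159 at 24 h. At 48 h they took 4.75, 4.32 and 7.70% in the vehicle replicates and 3.69, 5.67 and 3.82% in the ETC-159 replicates, so that V48r3 and E48r2 stood above the others. Over all tested genes the first principal component held 46.4% of the variance and the second 16.5%.

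After 24 h of ETC-159 the transcript of the drug's own target rose and most feedback genes of the Wnt pathway fell. PORCN (ENSG00000102312, chromosome X, 48508959 to 48520814) went from 91 ± 6.7 to 159 ± 3.89 CPM, a log2 fold change of 0.81 ± 0.05 (edgeR adjusted p = 2.1e-11). AXIN2 (ENSG00000168646, chromosome 17, 65528563 to 65561648), a scaffold of the beta-catenin destruction complex and a classic Wnt target, fell from 9.72 ± 0.488 to 1.97 ± 0.0362 CPM (-2.30 ± 0.11, adjusted p = 1.2e-12). NOTUM (ENSG00000185269, chromosome 17, 81952507 to 81961840), a secreted enzyme that removes the lipid from Wnt proteins, changed by -2.01 ± 0.17 and NKD1 (ENSG00000140807, chromosome 16, 50548396 to 50649249), which antagonises Dishevelled, by -1.84 ± 0.18. The paired ubiquitin ligases RNF43 (ENSG00000108375, chromosome 17, 58353676 to 58417595) and ZNRF3 (ENSG00000183579, chromosome 22, 28883572 to 29057488) changed by -0.90 ± 0.06 and -1.04 ± 0.12. The transcription factors SP5 (ENSG00000204335, chromosome 2, 170715337 to 170718078) and MYC (ENSG00000136997, chromosome 8, 127735434 to 127742951) changed by -2.21 ± 0.48 (adjusted p = 6.6e-04) and -0.73 ± 0.04 (adjusted p = 1.0e-11).

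Some textbook Wnt targets did not pass the test or were not tested. CCND1 (ENSG00000110092, chromosome 11, 69641156 to 69654474), which encodes cyclin D1, had a log2 fold change of -0.05 ± 0.04 (adjusted p = 0.271) at levels of 476 ± 14.1 and 459 ± 8.65 CPM. With library-size scaling it was called lower (-0.12, adjusted p = 0.0149), and also when mitochondrially encoded genes were removed before scaling (-0.11, adjusted p = 0.0186). LGR5, a receptor for R-spondins, was too low to be tested, with 8 to 10 counts in the vehicle and 1 to 2 in the ETC-159 libraries at 24 h. Of the 22 tested Wnt/beta-catenin targets and feedback regulators, 2 rose and 12 fell (2 and 12 adjusted over the list alone). Their median was -0.361 (camera adjusted p = 3.2e-07, adjusted p = 0.0113 with an estimated correlation). BMP4, a secreted growth factor, changed by -0.99 ± 0.04. Among the 22 Wnt ligands, receptors and secretion genes 10 rose and 3 fell (10 and 4 adjusted over the list alone), the median being 0.104 (camera adjusted p = 0.0878). WNT10A, a Wnt ligand, rose by 0.35 ± 0.06 and FZD7, a Frizzled receptor, changed by -0.65 ± 0.06. This list was called with offsets from the effective lengths (adjusted p = 0.0238).

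**Figure D1:**
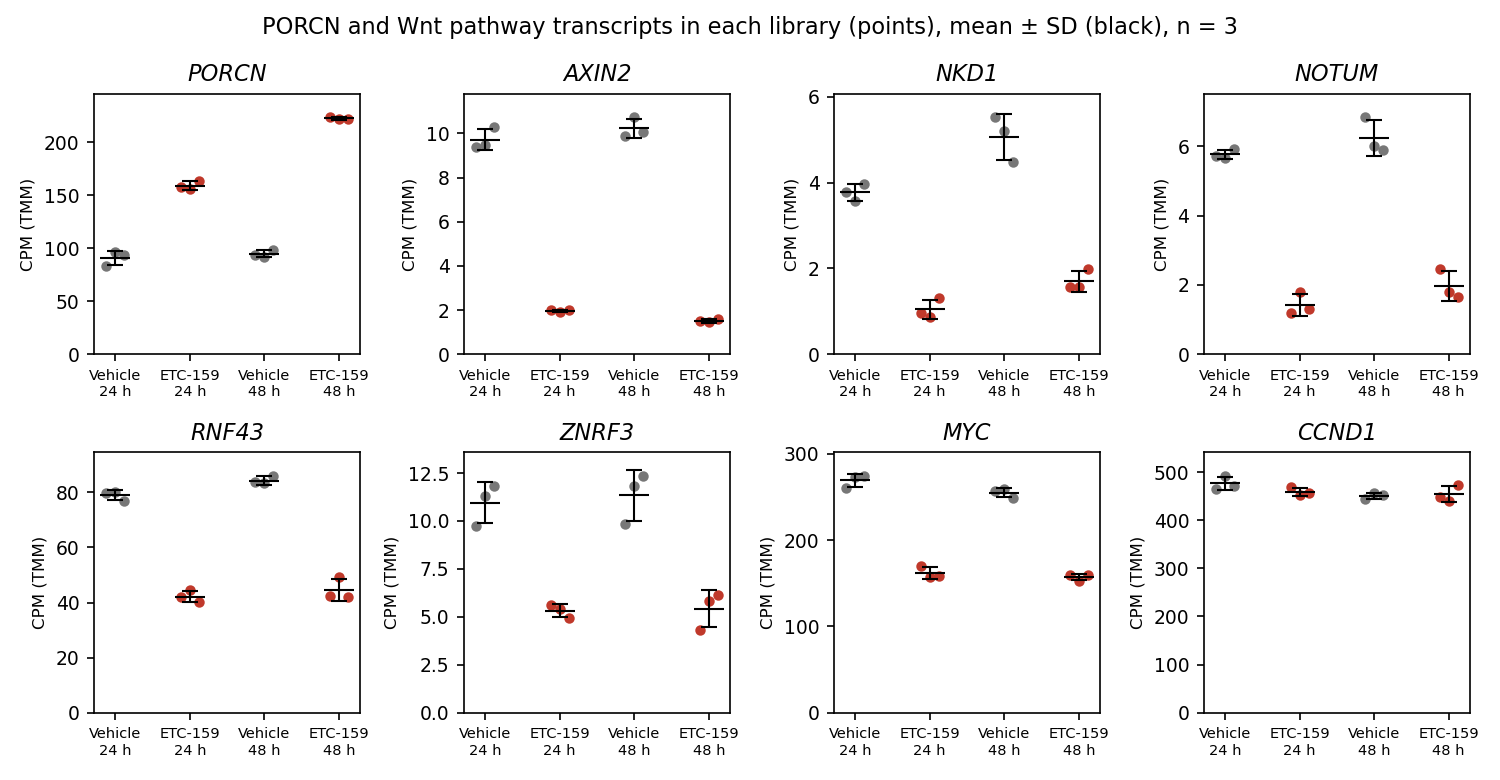
TMM-scaled CPM of PORCN and 7 Wnt pathway genes in each of the 12 libraries, grouped by treatment and time, with the mean and SD of 3 libraries in black. PORCN was higher in ETC-159 than in vehicle libraries at both times, AXIN2, NKD1, NOTUM, RNF43, ZNRF3 and MYC were lower, and CCND1 passed the test at neither time.

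At 24 h all 35 of 35 DNA replication and G1/S genes fell (all 35 adjusted over the list alone). Their median was -0.97 (camera adjusted p = 4.1e-31, adjusted p = 0.1 with an estimated correlation). MCM7, a subunit of the replicative helicase, fell from 564 ± 17 to 268 ± 7.93 CPM (-1.07 ± 0.06), and the primase subunit PRIM1 and clamp loader subunit RFC4 changed by -1.06 ± 0.06 and -0.93 ± 0.05. All 34 G2/M and mitosis genes fell as well (0 and 34 adjusted over the list alone). Their median was -0.821 (camera adjusted p = 2.8e-30, adjusted p = 0.1 with an estimated correlation). Cyclin B1 (CCNB1), the mitotic kinesin KIF2C and the checkpoint kinase BUB1B changed by -0.73 ± 0.06, -0.82 ± 0.06 and -0.93 ± 0.07. Homologous recombination and Fanconi anaemia repair genes fell in 24 of 24 cases (0 and 24 adjusted over the list alone). The median was -0.928 (camera adjusted p = 9.2e-18, adjusted p = 0.0596 with an estimated correlation). BRCA2, FANCD2 and BRIP1 changed by -1.02 ± 0.09, -0.98 ± 0.08 and -0.92 ± 0.08.

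MYC targets fell at 24 h in 29 of 30 (0 and 29 adjusted over the list alone). The median was -0.491 (camera adjusted p = 8.9e-21, adjusted p = 0.0642 with an estimated correlation). The nucleolar chaperone NPM1, the mitochondrial chaperonin HSPD1 and ornithine decarboxylase (ODC1) changed by -0.52 ± 0.04, -0.77 ± 0.05 and -0.59 ± 0.04. Of 40 ribosome biogenesis genes 39 fell and 0 rose (0 and 40 adjusted over the list alone). The median was -0.479 (camera adjusted p = 2.5e-21, adjusted p = 0.0593 with an estimated correlation). The snoRNP proteins NOP56, NOP58 and FBL changed by -0.68 ± 0.05, -0.57 ± 0.04 and -0.56 ± 0.05. Cytosolic ribosomal protein genes moved less, with 39 of 72 lower and 0 higher (0 and 40 adjusted over the list alone) and a median of -0.117 (camera adjusted p = 3.8e-04, adjusted p = 0.544 with an estimated correlation). With library size only that median was -0.183. RPSA, RPL3 and RPS23 changed by -0.20 ± 0.05, -0.16 ± 0.04 and -0.25 ± 0.05. In the list of CDK inhibitors and growth arrest 8 of 17 rose and 2 fell (9 and 2 adjusted over the list alone). The median was 0.187 (camera adjusted p = 0.0481, adjusted p = 0.279 with an estimated correlation). CDKN2B, an inhibitor of CDK4 and CDK6, rose by 1.02 ± 0.07, and the MYC antagonists MXD1 and MXD4 by 0.66 ± 0.04 and 0.80 ± 0.09. That list's call ended without 1 library in 6 cases, the adjusted p by library left out being E24r1 0.0561, E24r2 0.0539, E48r1 0.058, E48r2 0.058, V24r2 0.0741 and V48r3 0.0531, and it ended with RLE (0.0517), library size only (0.0614, median 0.121), the CPM filter (0.059), effective-length offsets (0.0585), mitochondrially encoded genes removed (0.0603) and without V48r3 and E48r2 together (0.0693).

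At 24 h, of 27 mucins and secretory differentiation genes 22 rose and 1 fell (22 and 1 adjusted over the list alone). The median was 0.77 (camera adjusted p = 5.0e-16, adjusted p = 0.00186 with an estimated correlation). The membrane mucin MUC1 went from 421 ± 13.4 to 726 ± 7.8 CPM (0.79 ± 0.04), and the glycosyltransferases GALNT5 and B3GNT3 rose by 0.66 ± 0.04 and 0.77 ± 0.05. Lists for both published tumour subtypes of pancreatic cancer rose. The classical subtype had 17 of 19 higher and 1 lower (17 and 1 adjusted over the list alone). The median was 0.727 (camera adjusted p = 4.0e-07, adjusted p = 0.166 with an estimated correlation). Keratin 20 (KRT20), the secretory disulfide isomerase AGR2 and the sialyltransferase ST6GALNAC1 changed by 0.98 ± 0.05, 0.79 ± 0.05 and 1.51 ± 0.15. The basal-like subtype had 15 of 23 higher and 1 lower (16 and 1 adjusted over the list alone). The median was 0.625 (camera adjusted p = 6.5e-09, adjusted p = 0.0133 with an estimated correlation). FAM83A, the cornified envelope protein SPRR1B and sciellin (SCEL) rose by 1.13 ± 0.05, 1.58 ± 0.09 and 0.91 ± 0.05.

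YAP/TEAD targets rose in 17 of 23 cases and fell in 2 (17 and 2 adjusted over the list alone). The median was 0.408 (camera adjusted p = 2.0e-09, adjusted p = 0.0113 with an estimated correlation). The matricellular protein CCN1, the IGF-binding protein IGFBP3 and the ectonucleotidase NT5E rose by 0.89 ± 0.05, 1.13 ± 0.04 and 0.58 ± 0.04. In the epithelial-mesenchymal transition list 10 of 19 rose and 0 fell (10 and 1 adjusted over the list alone). The median was 0.229 (camera adjusted p = 4.5e-05, adjusted p = 0.101 with an estimated correlation). Among its members the membrane protease MMP14 rose by 0.82 ± 0.04. The list also holds CDH1, the epithelial adhesion protein E-cadherin, chosen here after its value was seen, which rose by 0.64 ± 0.05. MAPK output genes were higher in 9 of 20 and lower in 3 (9 and 3 adjusted over the list alone). The median was 0.104 (camera adjusted p = 0.202). The phosphatase DUSP5 and the receptor EPHA2 changed by 0.77 ± 0.04 and 0.50 ± 0.04 and the transcription factor ETV4 by -0.42 ± 0.06.

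Cholesterol biosynthesis genes rose at 24 h in 20 of 24 cases and fell in 1 (21 and 1 adjusted over the list alone). The median was 0.257 (camera adjusted p = 3.9e-06, adjusted p = 0.101 with an estimated correlation). Lanosterol synthase (LSS) and the sterol desaturase SC5D rose by 0.60 ± 0.05 and 0.43 ± 0.05. Lysosome and autophagy genes rose in 22 of 28 and fell in 2 (22 and 2 adjusted over the list alone). The median was 0.216 (camera adjusted p = 5.1e-04, adjusted p = 0.3 with an estimated correlation). Cathepsin D (CTSD), prosaposin (PSAP) and the transcription factor TFE3 changed by 0.63 ± 0.05, 0.35 ± 0.05 and 0.28 ± 0.04. Replication-dependent histone genes rose in 7 of 10 and fell in 0 (7 and 0 adjusted over the list alone). The median was 0.59 (camera adjusted p = 0.00114, adjusted p = 0.158 with an estimated correlation). H1-2, H2BC21 and H2AC6 rose by 0.68 ± 0.08, 0.99 ± 0.08 and 1.01 ± 0.08; most histone mRNAs lack a poly(A) tail, so libraries of polyadenylated RNA sample only part of them. Interferon response genes rose in 11 of 28 and fell in 1 (9 and 1 adjusted over the list alone). The median was 0.193 (camera adjusted p = 0.0183, adjusted p = 0.588 with an estimated correlation). IFI27, IRF9 and OAS1 rose by 0.40 ± 0.06, 0.40 ± 0.05 and 0.75 ± 0.07, and the list's call ended without E24r2 (median 0.118, adjusted p = 0.0546), its median being 0.127 with library size only.

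The remaining lists did not pass the test at 24 h. Glycolysis and hypoxia genes were higher in 10 and lower in 3 of 25 (11 and 3 adjusted over the list alone), median 0.116 (camera adjusted p = 0.0501), and the list was called without 1 library in 3 cases, the adjusted p by library left out being E24r2 0.042, V24r2 0.0484 and V24r3 0.0351. Oxidative phosphorylation genes were higher in 2 and lower in 11 of 38 (2 and 11 adjusted over the list alone). The median was -0.0377 (camera adjusted p = 0.178). Of the 13 mitochondrially encoded mRNAs 0 were called by edgeR (0 at an unadjusted p under 0.05, 0 and 0 adjusted over the list alone). The median was 0.114 (camera adjusted p = 0.895). Unfolded protein response genes were higher in 12 and lower in 2 of 24 (12 and 4 adjusted over the list alone). The median was 0.151 (camera adjusted p = 0.0878). Notch targets were split 3 to 3 of 10 (3 and 3 adjusted over the list alone), median -0.0194 (camera adjusted p = 0.895), and BMP and TGF-beta targets 3 to 6 of 15 (3 and 6 adjusted over the list alone). The median was -0.102 (camera adjusted p = 0.154). For p53 targets 6 rose and 7 fell of 23 (7 and 7 adjusted over the list alone), the median and the test being negative (-0.106, camera adjusted p = 0.823) and the mean positive (0.0102). Markers of other cell types gave 3 higher and 1 lower of 5 stromal, immune and endothelial genes (3 and 1 adjusted over the list alone), median 0.444 (camera adjusted p = 0.0878), and 0 called of 5 acinar and endocrine genes by edgeR (1 at an unadjusted p under 0.05, 0 and 0 adjusted over the list alone). The median was -0.0703 (camera adjusted p = 0.726). CD68, a lysosomal protein also expressed outside macrophages, and lysozyme (LYZ), which is also on the classical list, changed by 0.88 ± 0.05 and -0.38 ± 0.05.

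Under the naming rule the largest rises at 24 h were in DUOX2 (ENSG00000140279, chromosome 15, 45092650 to 45114172), an oxidase that makes hydrogen peroxide (2.72 ± 0.21), RAB37 (ENSG00000172794, chromosome 17, 74670578 to 74747335), a small GTPase of secretory granules (2.58 ± 0.16), TP53INP2 (ENSG00000078804, chromosome 20, 34704339 to 34713439), an autophagy regulator (2.38 ± 0.10), SMPD3 (ENSG00000103056, chromosome 16, 68358327 to 68448508), a neutral sphingomyelinase (2.35 ± 0.22), VTCN1 (ENSG00000134258, chromosome 1, 117143587 to 117210960), an inhibitory ligand of T cells (2.18 ± 0.24), SMIM5 (ENSG00000204323, chromosome 17, 75633434 to 75641404), a small membrane protein (2.14 ± 0.20), and PSCA (ENSG00000167653, chromosome 8, 142670308 to 142682725), a surface antigen (2.04 ± 0.13). ALPG (ENSG00000163286, chromosome 2, 232406844 to 232410714), an alkaline phosphatase, rose by 2.20 ± 0.08, an uncertain value since reads can be shared with near-identical paralogs. The deepest falls, besides AXIN2, NOTUM and NKD1, were in AQP3 (ENSG00000165272, chromosome 9, 33441156 to 33447596), a water and glycerol channel that went from 344 ± 1.96 to 67.2 ± 3.4 CPM (-2.35 ± 0.06), CLDN2 (ENSG00000165376, chromosome X, 106900164 to 106930861), a pore-forming claudin (-2.04 ± 0.17), IGFL4 (ENSG00000204869, chromosome 19, 46039182 to 46077118), an IGF-like peptide (-1.91 ± 0.28), RIPPLY3 (ENSG00000183145, chromosome 21, 37006150 to 37019662), a transcriptional corepressor (-1.90 ± 0.24), and the homeobox gene DLX2 (ENSG00000115844, chromosome 2, 172099438 to 172102900) (-1.81 ± 0.25). Adjusted p for these genes ran from 5.7e-17 for AQP3 to 8.7e-06 for IGFL4.

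In total edgeR called 7140 of 14808 genes at 24 h (48.2%), 3786 higher and 3354 lower, of which 340 and 176 changed at least 2-fold. With library-size scaling the split was 2947 higher and 4291 lower, and with mitochondrially encoded genes removed 3124 and 4135. By glmTreat only 2936 genes were called as changed by more than 1.2-fold. Camera called 17 lists, 10 higher and 7 lower.

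After 48 h the same Wnt genes were called. PORCN stood at 94.8 ± 3.21 CPM in vehicle and 222 ± 1.05 CPM in ETC-159, a log2 fold change of 1.23 ± 0.05 (adjusted p = 1.8e-14), and AXIN2 changed by -2.76 ± 0.12, from 10.2 ± 0.44 to 1.51 ± 0.0765 CPM. NOTUM, NKD1, RNF43, ZNRF3, SP5 and MYC changed by -1.66 ± 0.16, -1.58 ± 0.16, -0.92 ± 0.06, -1.07 ± 0.12, -1.86 ± 0.44 and -0.70 ± 0.04, the highest adjusted p being 0.00134 for SP5. The NKD1 call did not pass with limma on log2(TPM + 0.1) (adjusted p = 0.0519). CCND1 had a log2 fold change of 0.01 ± 0.04 (adjusted p = 0.828), and LGR5 had 7 to 9 counts in the vehicle and 3 to 6 in the ETC-159 libraries. Wnt/beta-catenin targets and feedback regulators rose in 4 and fell in 13 of 22 cases (5 and 13 adjusted over the list alone). The median was -0.452 (camera adjusted p = 2.9e-05, adjusted p = 0.0302 with an estimated correlation). BMP4 changed by -1.12 ± 0.04. Of the Wnt ligands, receptors and secretion genes 10 rose and 6 fell (10 and 6 adjusted over the list alone). The median was 0.266 (camera adjusted p = 0.0705). WNT10A and FZD7 changed by 0.69 ± 0.06 and -0.72 ± 0.06. This list was called without E48r1 (adjusted p = 0.0457) and with effective-length offsets (adjusted p = 0.0249).

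DNA replication and G1/S genes fell at 48 h in 34 of 35 cases (0 and 34 adjusted over the list alone). The median was -1.01 (camera adjusted p = 4.2e-23, adjusted p = 0.13 with an estimated correlation). MCM7, PRIM1 and RFC4 changed by -1.02 ± 0.06, -1.31 ± 0.07 and -1.15 ± 0.05. All 34 G2/M genes fell (0 and 34 adjusted over the list alone), median -1.14 (camera adjusted p = 7.8e-38, adjusted p = 0.0738 with an estimated correlation), CCNB1 going from 238 ± 2.85 to 107 ± 11.9 CPM (-1.15 ± 0.06) and KIF2C and BUB1B changing by -1.16 ± 0.06 and -1.22 ± 0.07. Repair genes of homologous recombination and the Fanconi pathway fell in 24 of 24 (0 and 24 adjusted over the list alone). The median was -0.986 (camera adjusted p = 8.4e-14, adjusted p = 0.0848 with an estimated correlation). BRCA2, FANCD2 and BRIP1 changed by -1.38 ± 0.09, -1.14 ± 0.08 and -1.04 ± 0.09. MYC targets fell in 29 and rose in 1 of 30 (1 and 29 adjusted over the list alone). The median was -0.554 (camera adjusted p = 2.9e-18, adjusted p = 0.0782 with an estimated correlation). NPM1, HSPD1 and ODC1 changed by -0.73 ± 0.04, -0.85 ± 0.05 and -0.66 ± 0.04. Ribosome biogenesis genes fell in 38 of 40 (0 and 39 adjusted over the list alone). The median was -0.515 (camera adjusted p = 2.9e-18, adjusted p = 0.0738 with an estimated correlation). NOP58, FBL and NOP56 changed by -0.81 ± 0.04, -0.80 ± 0.05 and -0.76 ± 0.05. Cytosolic ribosomal protein genes now fell in 67 of 72 (0 and 68 adjusted over the list alone). The median was -0.33 (camera adjusted p = 3.3e-17, adjusted p = 0.191 with an estimated correlation). RPSA, RPL3 and RPS23 changed by -0.61 ± 0.05, -0.48 ± 0.04 and -0.57 ± 0.05. Nuclear genes of oxidative phosphorylation fell in 26 of 38 (0 and 26 adjusted over the list alone). The median was -0.19 (camera adjusted p = 5.3e-04, adjusted p = 0.434 with an estimated correlation). Cytochrome c1 (CYC1) and the ATP synthase subunits ATP5PO and ATP5F1B changed by -0.43 ± 0.05, -0.39 ± 0.04 and -0.34 ± 0.04.

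Mucins and secretory genes rose in 23 and fell in 2 of 27 (24 and 2 adjusted over the list alone). The median was 0.818 (camera adjusted p = 1.8e-13, adjusted p = 0.00275 with an estimated correlation). MUC1, B3GNT3 and GALNT5 changed by 1.09 ± 0.04, 0.92 ± 0.05 and 0.82 ± 0.04. For the classical subtype 15 of 19 rose and 2 fell (15 and 2 adjusted over the list alone). The median was 0.604 (camera adjusted p = 5.9e-05, adjusted p = 0.246 with an estimated correlation). ST6GALNAC1, KRT20 and AGR2 changed by 2.00 ± 0.12, 1.09 ± 0.05 and 0.88 ± 0.05. For the basal-like subtype 15 of 23 rose and 2 fell (15 and 2 adjusted over the list alone). The median was 0.561 (camera adjusted p = 1.8e-09, adjusted p = 0.0133 with an estimated correlation). SPRR1B, FAM83A and SCEL changed by 2.15 ± 0.10, 1.60 ± 0.05 and 0.85 ± 0.05. YAP/TEAD targets rose in 18 and fell in 1 of 23 (18 and 1 adjusted over the list alone), median 0.521 (camera adjusted p = 9.0e-15, adjusted p = 0.00275 with an estimated correlation), CCN1 going from 45.9 ± 2.98 to 145 ± 4.93 CPM (1.66 ± 0.05) and IGFBP3 and NT5E rising by 1.16 ± 0.04 and 0.97 ± 0.04. Epithelial-mesenchymal transition genes rose in 10 and fell in 1 of 19 (10 and 1 adjusted over the list alone). The median was 0.603 (camera adjusted p = 5.0e-07, adjusted p = 0.0738 with an estimated correlation). MMP14 rose by 0.98 ± 0.04. E-cadherin (CDH1) also rose (0.60 ± 0.05).

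Glycolysis and hypoxia genes rose in 14 and fell in 3 of 25 (15 and 3 adjusted over the list alone). The median was 0.176 (camera adjusted p = 7.5e-04, adjusted p = 0.307 with an estimated correlation). The lactate exporter SLC16A3, NDRG1 and hexokinase 2 (HK2) changed by 0.80 ± 0.05, 0.77 ± 0.04 and 0.75 ± 0.05. Lysosome genes rose in 20 and fell in 2 of 28 (21 and 3 adjusted over the list alone). The median was 0.247 (camera adjusted p = 0.00131, adjusted p = 0.361 with an estimated correlation). CTSD, PSAP and TFE3 changed by 0.75 ± 0.05, 0.50 ± 0.05 and 0.38 ± 0.04. Histone genes rose in 6 of 10 (6 and 0 adjusted over the list alone). The median was 0.611 (camera adjusted p = 0.00456, adjusted p = 0.222 with an estimated correlation). H1-2 changed by 1.02 ± 0.07. MAPK output genes rose in 11 and fell in 4 of 20 (12 and 4 adjusted over the list alone), median 0.27 (camera adjusted p = 0.0493, adjusted p = 0.127 with an estimated correlation), EPHA2 and DUSP5 rising by 0.60 ± 0.04 and 0.50 ± 0.04 and ETV4 changing by -0.76 ± 0.06. The MAPK call ended without E24r1, E48r1 or V48r2 (adjusted p = 0.0536, 0.0595 and 0.0621), with RLE or library-size scaling (0.0507 and 0.0685), with the CPM filter (0.0609) and with mitochondrially encoded genes removed (0.0558).

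Cholesterol biosynthesis genes were not called as a group at 48 h. In this list 8 rose and 6 fell of 24 (9 and 6 adjusted over the list alone), with a negative median (-0.0279), a positive mean (0.031) and a test pointing up (camera adjusted p = 0.775), and LSS and SC5D changed by 0.30 ± 0.05 and 0.33 ± 0.05. CDK inhibitors were higher in 8 and lower in 2 of 17 (8 and 2 adjusted over the list alone). The median was 0.229 (camera adjusted p = 0.0897). CDKN2B changed by 0.86 ± 0.07. Interferon genes were higher in 17 and lower in 2 of 28 (18 and 2 adjusted over the list alone), median 0.311 (camera adjusted p = 0.0538), a list called with effective-length offsets (adjusted p = 0.0172) and without 1 library in 8 cases, the adjusted p by library left out being E24r2 0.0355, E24r3 0.0418, E48r3 0.00738, V24r1 0.0408, V24r2 0.042, V24r3 0.049, V48r1 0.0376 and V48r2 0.0262. OAS1 and IFI27 rose by 0.44 ± 0.06 and 0.51 ± 0.06. The unfolded protein response list had 12 higher and 4 lower of 24 (12 and 4 adjusted over the list alone). The median was 0.137 (camera adjusted p = 0.129). The membrane protein HERPUD1, calreticulin (CALR) and the phosphatase subunit PPP1R15A changed by 0.57 ± 0.04, 0.36 ± 0.04 and 0.36 ± 0.05.

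Notch targets gave 3 higher and 1 lower of 10 (3 and 1 adjusted over the list alone). The median was 0.107 (camera adjusted p = 0.661). The repressor HES2, the receptor NOTCH3 and the glycosyltransferase LFNG changed by 1.33 ± 0.20, -0.59 ± 0.10 and 0.26 ± 0.06. BMP and TGF-beta targets gave 6 and 5 of 15 (6 and 6 adjusted over the list alone), median 0.0121 (camera adjusted p = 0.906), a sign that turned with library-size scaling (-0.0414) and with mitochondrially encoded genes removed (-0.0053). BAMBI, a pseudoreceptor, changed by -0.94 ± 0.04 and LTBP2, a matrix protein, rose by 1.02 ± 0.08. For p53 targets 6 rose and 5 fell of 23 (6 and 5 adjusted over the list alone), the median being negative (-0.047) and the mean (0.0172) and test positive (camera adjusted p = 0.906). The death receptor TNFRSF10B, PLK3 and PHLDA3 changed by 0.40 ± 0.04, 0.87 ± 0.08 and 0.50 ± 0.06. Stromal, immune and endothelial markers were higher in 4 and lower in 1 of 5 (4 and 1 adjusted over the list alone), median 0.924 (camera adjusted p = 0.0705), called without E48r2 (adjusted p = 0.0475). CD14, CD68 and LYZ changed by 0.94 ± 0.08, 0.92 ± 0.05 and -0.77 ± 0.05. No acinar or endocrine marker was called by edgeR (0 of 5, 0 at an unadjusted p under 0.05, 0 and 0 adjusted over the list alone), with a positive median (0.178) and mean (0.0255) and a test pointing down (camera adjusted p = 0.929). Mitochondrially encoded mRNAs also had 0 calls of 13 by edgeR (0 at an unadjusted p under 0.05, 0 and 0 adjusted over the list alone), median -0.434 (camera adjusted p = 0.345), and this list was called lower without V48r3 and E48r2 (median -0.317, adjusted p = 0.0298).

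The largest rises at 48 h, besides DUOX2 (3.47 ± 0.17), SMPD3 (3.07 ± 0.17) and PSCA (2.69 ± 0.12), were in GUCA2B (ENSG00000044012, chromosome 1, 42153410 to 42155820), the hormone uroguanylin (3.06 ± 0.17), and MUC5B (ENSG00000117983, chromosome 11, 1223066 to 1262172), a gel-forming mucin (2.84 ± 0.21). Uncertain values were those of PSG3 (ENSG00000221826, chromosome 19, 42721638 to 42740481) and PSG1 (ENSG00000231924, chromosome 19, 42866464 to 42879822), near-identical pregnancy-specific glycoproteins (3.12 ± 0.30 and 2.75 ± 0.35), and RAB43 (ENSG00000172780, chromosome 3, 129087569 to 129122801), which has readthrough transcripts (2.84 ± 0.46). The deepest falls, besides AXIN2, RIPPLY3 (-2.82 ± 0.28), IGFL4 (-2.23 ± 0.28) and CLDN2 (-2.07 ± 0.18), were in AQP3, from 208 ± 14 to 29.4 ± 2.54 CPM (-2.82 ± 0.06), PLA2G4A (ENSG00000116711, chromosome 1, 186828949 to 186988981), a cytosolic phospholipase (-2.32 ± 0.20), and EDAR (ENSG00000135960, chromosome 2, 108894471 to 108989372), the ectodysplasin receptor (-2.22 ± 0.06). The readthrough gene TGIF2-RAB5IF (ENSG00000259399, chromosome 20, 36574553 to 36612384) had -3.40 ± 1.12 (adjusted p = 0.0302), an uncertain value whose call ended without E48r1, E48r2, V48r1 or V48r2 (adjusted p = 0.0879, 0.0922, 0.0626 and 0.0813), without the filter (0.0569) and without V48r3 and E48r2 together (0.0981).

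At 48 h edgeR called 8100 of 14808 genes (54.7%), 4065 higher and 4035 lower, of which 491 and 340 changed at least 2-fold. With library size only the split was 3487 to 4775. By glmTreat 3996 genes were called as changed by more than 1.2-fold. Camera called 17 lists, 9 higher and 8 lower. The comparisons at 24 h and 48 h share no library, and 5736 genes were called in both. Of these 5693 (99.3%) had the same direction, 2901 higher and 2792 lower, where independent lists of these sizes would share 1039 and 913.9, and 43 had opposite directions. Across all tested genes, which are not independent replicates, the fold changes correlated with Pearson's r = 0.654 and Spearman's rho = 0.749. Among the genes with the same direction 3697 (64.9%) had the larger change at 48 h.

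**Figure D2:**
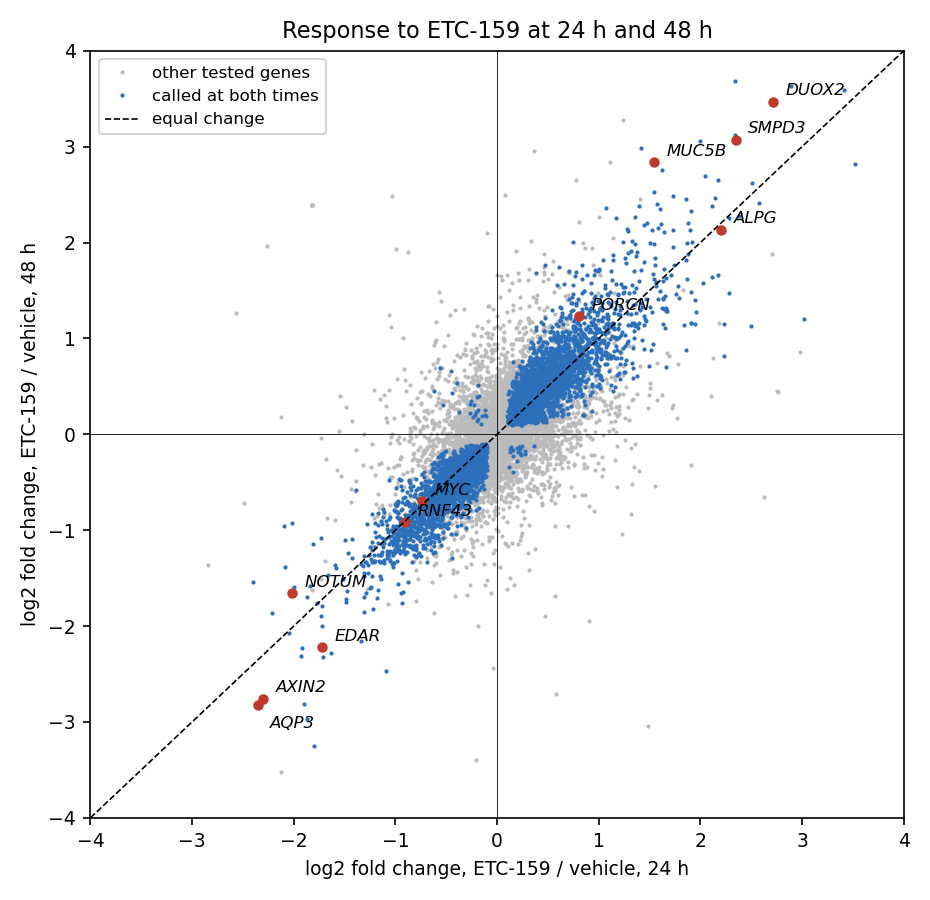
Log2 fold change of ETC-159 over vehicle at 24 h (horizontal) and 48 h (vertical) for the tested genes, with genes called at both times in blue, 11 named genes in red and a dashed line of equal change. In both axes the range is limited to 4 on either side of 0, and 13 genes lie outside it.

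**Figure D3:**
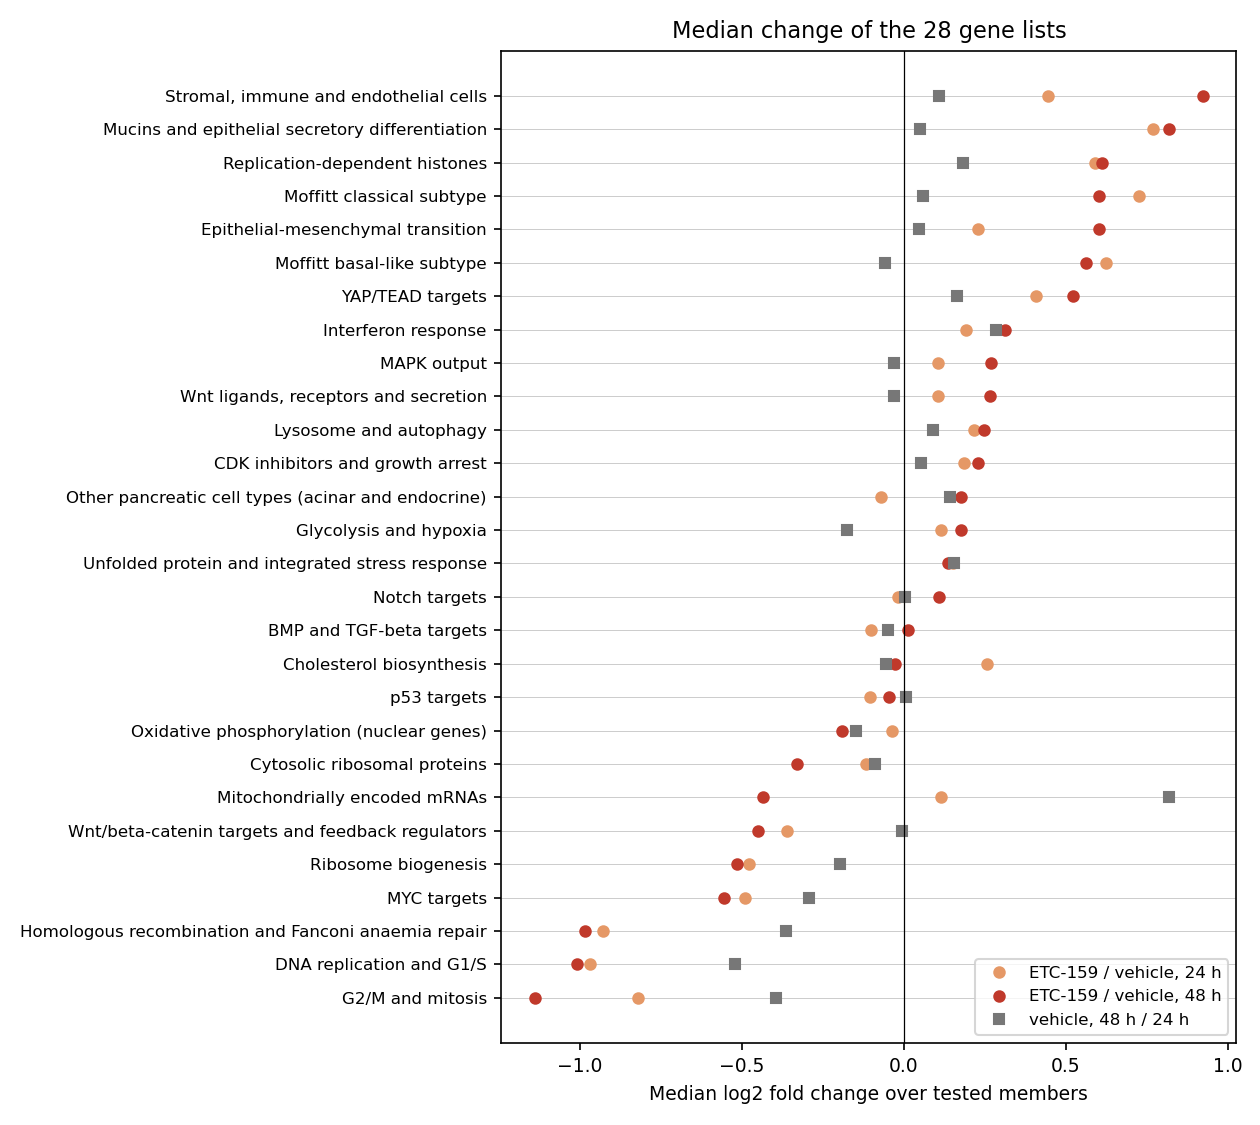
Median log2 fold change over the tested members of each of the 28 gene lists for ETC-159 over vehicle at 24 h (orange) and 48 h (red) and for vehicle at 48 h over 24 h (grey squares). Replication, G2/M and repair genes lie at the low end at both times, and mitochondrially encoded mRNAs have the highest median in vehicle (0.818).

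The difference between the responses at 48 h and 24 h was tested directly. PORCN rose more at 48 h (difference 0.42 ± 0.07, adjusted p = 6.5e-04), as did CCN1 (0.78 ± 0.07), FAM83A (0.47 ± 0.06), NT5E (0.40 ± 0.05) and SLC16A3 (0.41 ± 0.06). AQP3 and EDAR fell further (-0.47 ± 0.08 and -0.50 ± 0.09). Cytosolic ribosomal protein genes fell further in 45 of 72 cases (0 and 62 adjusted over the list alone). The median was -0.216 (camera adjusted p = 8.2e-29, adjusted p = 0.235 with an estimated correlation). RPSA had a difference of -0.41 ± 0.07 and RPL3 of -0.32 ± 0.05. Cholesterol biosynthesis genes had a lower response in 16 and a higher one in 1 of 24 (1 and 18 adjusted over the list alone), median -0.277 (camera adjusted p = 6.0e-14, adjusted p = 0.0551 with an estimated correlation), LSS having a difference of -0.30 ± 0.07.

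**Figure D4:**
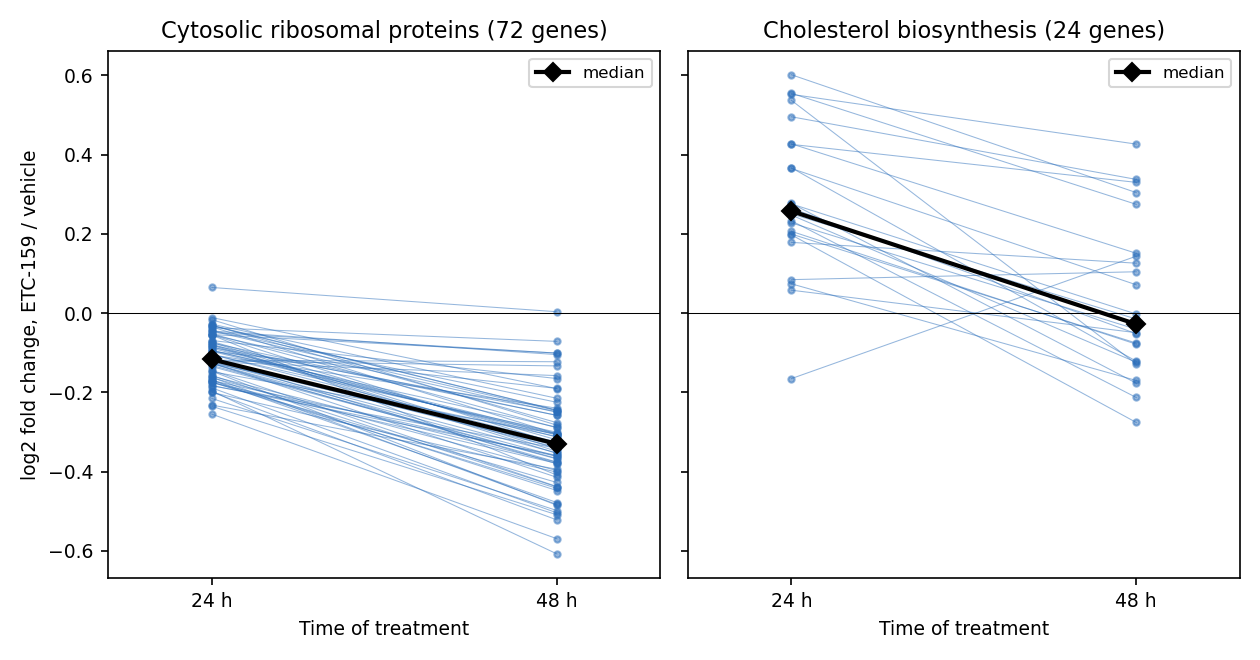
Log2 fold change of ETC-159 over vehicle at 24 h and 48 h for each tested cytosolic ribosomal protein gene (left, 72 genes) and cholesterol biosynthesis gene (right, 24 genes), a line joining the values of a gene and black diamonds marking the medians. The median moved from -0.117 to -0.330 for the ribosomal protein genes and from 0.257 to -0.0279 for the cholesterol genes.

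G2/M genes fell further at 48 h in 9 of 34 (0 and 18 adjusted over the list alone). The median was -0.285 (camera adjusted p = 1.5e-12, adjusted p = 0.479 with an estimated correlation), -0.434 without E48r3 and -0.178 without V48r3 and E48r2 together. CCNB1 had a difference of -0.42 ± 0.08. Nuclear oxidative phosphorylation genes had a lower response in 9 of 38 (0 and 12 adjusted over the list alone). The median was -0.122 (camera adjusted p = 2.0e-06, adjusted p = 0.479 with an estimated correlation). YAP/TEAD targets had a higher response in 5 of 23 (5 and 0 adjusted over the list alone), median 0.125 (camera adjusted p = 5.4e-07, adjusted p = 0.0551 with an estimated correlation), as had glycolysis genes in 6 of 25 (9 and 1 adjusted over the list alone), median 0.0811 (camera adjusted p = 7.3e-04, adjusted p = 0.479 with an estimated correlation), and BMP and TGF-beta targets in 3 of 15 (4 and 0 adjusted over the list alone). The median was 0.062 (camera adjusted p = 0.00936, adjusted p = 0.117 with an estimated correlation). The glycolysis median was 0.0503 without E24r1, 0.131 without E48r2, 0.0195 without E48r3 and 0.157 without V48r3 and E48r2 together, and the BMP and TGF-beta median 0.03 with the CPM filter, 0.112 with effective-length offsets, 0.114 without E48r3 and 0.0989 with mitochondrially encoded genes removed. For epithelial-mesenchymal transition genes 3 had a higher and 2 a lower response of 19 (8 and 2 adjusted over the list alone). The median was 0.178 (camera adjusted p = 0.0077, adjusted p = 0.425 with an estimated correlation). The basal-like list was called with 5 members higher of 23 (6 and 1 adjusted over the list alone) but had no stable sign of the median, which was 0.0142 (camera adjusted p = 0.0423, adjusted p = 0.425 with an estimated correlation), -0.0278 without E48r1, -0.000671 without E48r3, -0.00451 without V24r2 and at most 0.0565, without V48r3 and E48r2 together. Its call ended without 1 library in 6 cases, the adjusted p by library left out being E24r1 0.0954, E48r1 0.0867, E48r3 0.069, V24r3 0.0816, V48r1 0.0562 and V48r2 0.0646. The mitochondrially encoded list was called lower (median -0.528, camera adjusted p = 0.0423, adjusted p = 0.822 with an estimated correlation) with 0 of 13 members called by edgeR (0 at an unadjusted p under 0.05, 0 and 0 adjusted over the list alone), beside mitochondrial shares that reached 7.70% in V48r3 and 5.67% in E48r2. Its call ended with the CPM filter (adjusted p = 0.0575) and without 1 library in 7 cases, the adjusted p by library left out being E24r1 0.08, E24r3 0.0542, E48r1 0.236, E48r3 0.149, V24r1 0.128, V24r3 0.0886 and V48r3 0.391, and without V48r3 alone the median was -0.201. The other 18 lists had adjusted p from 0.0848 to 0.990, of which MAPK output was called with effective-length offsets, without V48r3 and E48r2, and with mitochondrially encoded genes removed (adjusted p = 0.0374, 0.0469 and 0.0333). Without E48r3 the G1/S, repair, MYC target and ribosome biogenesis lists were also called (adjusted p = 8.5e-06, 0.0121, 0.0167 and 0.0346). In 5 of the other lists signs differed, the median being negative and the mean and test positive for Wnt ligands, the mean alone negative for the unfolded protein response, and the test alone pointing down for CDK inhibitors, the classical subtype and interferon response.

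Under the naming rule the genes with the largest differences had group means of at most 6.41 CPM, the highest being that of CARNS1 in ETC-159 at 48 h. DMBT1 (ENSG00000187908, chromosome 10, 122560665 to 122643736), a secreted scavenger receptor protein (1.67 ± 0.31), CCDC183 (ENSG00000213213, chromosome 9, 136796338 to 136807741), a coiled-coil protein (1.61 ± 0.38), SERPINB4 (ENSG00000206073, chromosome 18, 63637259 to 63644256), a protease inhibitor (1.56 ± 0.32), ARC (ENSG00000198576, chromosome 8, 142611049 to 142614479), known from neuronal plasticity (1.48 ± 0.39), and CARNS1 (ENSG00000172508, chromosome 11, 67414968 to 67425607), carnosine synthase (1.41 ± 0.36), had the highest differences. SLC7A8 (ENSG00000092068, chromosome 14, 23125295 to 23183674), an amino acid transporter (-1.31 ± 0.26), ACSL1 (ENSG00000151726, chromosome 4, 184755595 to 184826818), an acyl-CoA synthetase (-1.28 ± 0.29), LY6G6C (ENSG00000204421, chromosome 6, 31718648 to 31721746), a GPI-anchored protein (-1.17 ± 0.28), HYAL1 (ENSG00000114378, chromosome 3, 50299890 to 50312381), a hyaluronidase (-0.98 ± 0.27), and NSFP1 (ENSG00000260075, chromosome 17, 46372855 to 46487141), a pseudogene of uncertain value (-0.99 ± 0.28), had the lowest. The call of CARNS1 ended without V24r2 (adjusted p = 0.0848). By library left out, adjusted p at or above the threshold were E24r2 0.0691, E24r3 0.0708, E48r2 0.061, V24r1 0.0668, V24r3 0.0593, V48r1 0.0661 and V48r2 0.0813 for ARC, E24r2 0.0524, E24r3 0.0584, E48r3 0.0565, V24r2 0.0776, V24r3 0.096, V48r2 0.0716 and V48r3 0.0624 for HYAL1 and E24r1 0.072, E24r3 0.115, E48r1 0.0663, E48r2 0.0882, V24r2 0.107, V24r3 0.117, V48r1 0.101, V48r2 0.121 and V48r3 0.0593 for NSFP1. Without V48r3 and E48r2 together the calls of CCDC183, CARNS1, ACSL1, LY6G6C, HYAL1 and NSFP1 ended (adjusted p = 0.0516, 0.0804, 0.0638, 0.0683, 0.0734 and 0.105).

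Altogether 1076 genes (7.27%) differed between the times, 499 with a higher and 577 with a lower value at 48 h, of which 600 had the same sign and a larger change at 48 h, 166 the same sign and a smaller change, and 310 opposite signs. The split into higher and lower values was 614 to 460 with RLE scaling, 687 to 490 by DESeq2 and 767 to 402 with mitochondrially encoded genes removed. It was 241 to 47 with limma on log2(TPM + 1), where 288 genes were called. The count fell to 404 with effective-length offsets, to 709 without V48r3 and E48r2, to 48 by glmTreat at 1.2-fold, and to 602, 633, 637, 588, 652 and 517 without E24r2, E24r3, V24r2, V24r3, V48r1 and V48r2.

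Vehicle cells themselves changed between 24 h and 48 h, which gives the background for the drug's time course. Genes of DNA replication and G1/S fell in 33 of 35 (0 and 34 adjusted over the list alone), median -0.521 (camera adjusted p = 5.1e-22, adjusted p = 0.386 with an estimated correlation), G2/M in 33 of 34 (0 and 33 adjusted over the list alone), median -0.394 (camera adjusted p = 4.3e-18, adjusted p = 0.386 with an estimated correlation), and MYC targets in 27 of 30 (1 and 27 adjusted over the list alone). The median was -0.293 (camera adjusted p = 8.7e-19, adjusted p = 0.386 with an estimated correlation). Ribosome biogenesis genes fell in 27 and rose in 1 of 40 (1 and 28 adjusted over the list alone), median -0.197 (camera adjusted p = 1.8e-10, adjusted p = 0.386 with an estimated correlation), repair genes fell in 19 of 24 (0 and 20 adjusted over the list alone), median -0.364 (camera adjusted p = 1.1e-07, adjusted p = 0.386 with an estimated correlation), and ribosomal protein genes in 28 of 72 (1 and 29 adjusted over the list alone). The median was -0.0902 (camera adjusted p = 2.0e-04, adjusted p = 0.543 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 24 of 38 (0 and 24 adjusted over the list alone), median -0.149 (camera adjusted p = 1.5e-06, adjusted p = 0.543 with an estimated correlation), while mitochondrially encoded mRNAs rose in 11 of 13 (12 and 0 adjusted over the list alone), median 0.818 (camera adjusted p = 6.7e-04, adjusted p = 0.543 with an estimated correlation), beside the mitochondrial share of 7.70% in V48r3, without which the median was 0.511 (0.512 without V48r3 and E48r2 together). Glycolysis and hypoxia genes fell in 14 and rose in 4 of 25 (4 and 14 adjusted over the list alone). The median was -0.176 (camera adjusted p = 0.00388, adjusted p = 0.543 with an estimated correlation). Interferon genes rose in 18 of 28 (20 and 0 adjusted over the list alone), median 0.285 (camera adjusted p = 1.3e-05, adjusted p = 0.543 with an estimated correlation), and YAP/TEAD targets in 13 with 1 lower of 23 (13 and 3 adjusted over the list alone). The median was 0.165 (camera adjusted p = 0.00219, adjusted p = 0.386 with an estimated correlation).

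The unfolded protein response and lysosome lists rose in vehicle with medians of 0.156 (12 rose and 6 fell of 24, 14 and 6 adjusted over the list alone, camera adjusted p = 0.0429, adjusted p = 0.543 with an estimated correlation) and 0.0912 (12 rose and 2 fell of 28, 14 and 3 adjusted over the list alone, camera adjusted p = 0.0442, adjusted p = 0.543 with an estimated correlation). The first call ended without 1 library in 5 cases, the adjusted p by library left out being E24r1 0.0532, E48r2 0.073, V24r2 0.0941, V24r3 0.0537 and V48r1 0.072, with RLE scaling (0.0615), without V48r3 and E48r2 (0.0694) and with mitochondrially encoded genes removed (0.0712). The second ended without 1 library in 6 cases, the adjusted p by library left out being E24r1 0.0531, E48r2 0.071, V24r1 0.0525, V24r2 0.0957, V48r1 0.0744 and V48r2 0.0902, with RLE scaling (0.0808) and with mitochondrially encoded genes removed (0.0843, median 0.0593). Wnt targets were not called as a group in vehicle, with 3 higher and 5 lower of 22 (3 and 5 adjusted over the list alone), a median of -0.00598 and a mean of 0.0143 (camera adjusted p = 0.353), and PORCN and AXIN2 had log2 fold changes of 0.06 ± 0.05 and 0.07 ± 0.09 (adjusted p = 0.354 and 0.545). The 15 lists that were not called had adjusted p from 0.121 to 0.992. In 4 of these 15 the signs differed, the mean alone being positive for Wnt targets and Wnt ligands, the mean alone negative for Notch targets and the test alone pointing down for p53 targets.

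In vehicle PHGDH (ENSG00000092621, chromosome 1, 119648411 to 119744218), which catalyses the entry step of serine synthesis, went from 35.9 ± 10.9 to 141 ± 14.1 CPM (1.97 ± 0.25), and ALDH1L2 (ENSG00000136010, chromosome 12, 105019784 to 105107643), a mitochondrial folate enzyme, rose by 2.10 ± 0.24. ADCY4 (ENSG00000129467, chromosome 14, 24318349 to 24335093), an adenylate cyclase, rose by 2.00 ± 0.24. Values for the readthrough gene CRYZL2P-SEC16B (ENSG00000254154, chromosome 1, 177928788 to 178038007) (2.23 ± 0.33) and the antisense gene DICER1-AS1 (ENSG00000235706, chromosome 14, 95157645 to 95181475) (1.79 ± 0.29) are uncertain. The largest falls were in KRT6A (ENSG00000205420, chromosome 12, 52487176 to 52493257), a stress keratin (-1.74 ± 0.22), TMEM160 (ENSG00000130748, chromosome 19, 47045909 to 47048624), a transmembrane protein (-1.19 ± 0.33), SPRR1B (ENSG00000169469, chromosome 1, 153031203 to 153032900) (-1.01 ± 0.11), IL1RL1 (ENSG00000115602, chromosome 2, 102311502 to 102352037), the receptor for interleukin 33 (-0.99 ± 0.12), and BCYRN1 (ENSG00000236824, chromosome 2, 47335315 to 47335514), a small cytoplasmic RNA with many similar sequences in the genome and thus uncertain (-0.97 ± 0.22). The TMEM160 call ended without V24r3, V48r1 or V48r2 (adjusted p = 0.0521, 0.0512 and 0.0695), and that of BCYRN1 with limma on log2(TPM + 1) and log2(TPM + 0.1) (0.138 and 0.0956). In total 5447 genes (36.8%) were called, 2585 higher and 2862 lower, of which 217 and 16 changed at least 2-fold. The split was 3299 to 2187 with upper-quartile scaling, 2261 to 3357 with RLE, 1928 to 3111 by DESeq2 and 2143 to 3498 with mitochondrially encoded genes removed. The total fell to 3247 with limma on log2(TPM + 1), and by glmTreat 889 genes were called as changed by more than 1.2-fold. Camera called 13 lists, 5 higher and 8 lower.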

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

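The omission of V48r3 and E48r2 together, the comparison with genes matched on length and abundance, all PORCN tests and the counts of other splits of the samples were chosen after the result was seen. The responses at 48 h and 24 h differed, by the test of the difference itself, for 1076 genes. Without E24r2, E24r3, V24r2, V24r3, V48r1 or V48r2 the number was 602, 633, 637, 588, 652 and 517, and without V48r3 and E48r2 together it was 709. Of 100 splits drawn, regrouping times within each treatment, 4, the real one included, called at least as many genes, the highest other 2019. Of 14 others in which 1 treatment kept its times 9 called genes, against 0 of 85 with both regrouped. Gene counts thus carry the change with time. For lists 56 gave at least the 10 called, up to 15 in both kinds. Neither count decides on chance.

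The other comparisons have 10 splits each, too few for a share under 0.05. Real splits called 7140, 8100 and 5447 genes at 24 h, 48 h and for vehicle. All others called 0, but mix the groups, which widens the spread, so this cannot decide on chance. For lists the real split at 24 h called 17 and the highest other 19, with 3 splits reaching the real value, at 48 h 17 and 18, with 2, and for vehicle 13 and 11, with 1.

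Named genes with a positive difference between 48 h and 24 h whose call held without each library in turn included CCN1 (0.78 ± 0.07), FAM83A (0.47 ± 0.06), NT5E (0.40 ± 0.05), SLC16A3 (0.41 ± 0.06), PORCN (0.42 ± 0.07), MUC1 (0.31 ± 0.06), DMBT1 (1.67 ± 0.31), SERPINB4 (1.56 ± 0.32), GUCA2B (1.06 ± 0.24) and CCDC183 (1.61 ± 0.38). Those with a negative difference included RPSA (-0.41 ± 0.07), RPL3 (-0.32 ± 0.05), RPS23 (-0.31 ± 0.06), EDAR (-0.50 ± 0.09), AQP3 (-0.47 ± 0.08), LYZ (-0.39 ± 0.07), SLC7A8 (-1.31 ± 0.26), CCNB1 (-0.42 ± 0.08), LSS (-0.30 ± 0.07), DUSP5 (-0.27 ± 0.06), ACSL1 (-1.28 ± 0.29) and LY6G6C (-1.17 ± 0.28).

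Of 39 named genes reported 17 lost the call without at least 1 library, whose adjusted p follows each difference. Positive differences were those of MUC5B (1.29 ± 0.31, V24r2 0.0577 and V48r2 0.0624), which also failed with effective-length offsets (0.634), SPRR1B (0.57 ± 0.14, V24r3 0.0515), CD14 (0.49 ± 0.12, E24r2 0.056 and V24r3 0.0724), CARNS1 (1.41 ± 0.36, V24r2 0.0848), WNT10A (0.34 ± 0.09, E24r2 0.0544, E24r3 0.0679, E48r2 0.0578, V24r3 0.0754 and V48r2 0.0519), ARC (1.48 ± 0.39, E24r2 0.0691, E24r3 0.0708, E48r2 0.061, V24r1 0.0668, V24r3 0.0593, V48r1 0.0661 and V48r2 0.0813), PLK3 (0.41 ± 0.12, E24r2 0.0587, E24r3 0.105, E48r1 0.0511, E48r2 0.108, V24r2 0.121, V24r3 0.0653, V48r2 0.128 and V48r3 0.0636) and LTBP2 (0.42 ± 0.12, E24r2 0.115, E24r3 0.0938, E48r2 0.103, E48r3 0.0796, V24r1 0.122, V24r3 0.0694, V48r1 0.089 and V48r2 0.13). Negative ones were those of ATP5PO (-0.25 ± 0.06, V24r2 0.0535), ETV4 (-0.34 ± 0.08, V48r2 0.0537), KIF2C (-0.34 ± 0.09, E24r2 0.0657 and E48r2 0.063), NOP58 (-0.24 ± 0.06, E24r3 0.0759, V24r2 0.0525, V48r2 0.0637 and V48r3 0.0502), HYAL1 (-0.98 ± 0.27, E24r2 0.0524, E24r3 0.0584, E48r3 0.0565, V24r2 0.0776, V24r3 0.096, V48r2 0.0716 and V48r3 0.0624), NPM1 (-0.21 ± 0.06, E24r2 0.0544, E24r3 0.0995, V24r1 0.0512, V24r2 0.0654, V24r3 0.0893, V48r1 0.0747 and V48r2 0.0853), FBL (-0.23 ± 0.07, E24r1 0.0633, E24r2 0.0802, E24r3 0.0647, E48r2 0.0773, V24r1 0.0803, V24r2 0.0577, V24r3 0.0752, V48r1 0.0963, V48r2 0.0693 and V48r3 0.0531), ATP5F1B (-0.20 ± 0.06, E24r1 0.0534, E24r2 0.0862, E24r3 0.0974, V24r1 0.0735, V24r2 0.095, V24r3 0.0771, V48r1 0.0868 and V48r2 0.1) and NSFP1 (-0.99 ± 0.28, E24r1 0.072, E24r3 0.115, E48r1 0.0663, E48r2 0.0882, V24r2 0.107, V24r3 0.117, V48r1 0.101, V48r2 0.121 and V48r3 0.0593).

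Among lists the median difference was -0.216 for cytosolic ribosomal proteins, -0.285 for G2/M and mitosis, -0.277 for cholesterol biosynthesis, -0.122 for nuclear oxidative phosphorylation genes and -0.528 for mitochondrially encoded mRNAs. It was 0.178 for epithelial-mesenchymal transition, 0.125 for YAP/TEAD targets, 0.0811 for glycolysis and hypoxia, 0.062 for BMP and TGF-beta targets and 0.0142 for the basal-like subtype. The basal-like median turned negative without E48r1 (-0.0278), E48r3 (-0.000671) and V24r2 (-0.00451), and its call ended without 1 library in 6 cases (E24r1 0.0954, E48r1 0.0867, E48r3 0.069, V24r3 0.0816, V48r1 0.0562 and V48r2 0.0646). The mitochondrial call ended in 7 (E24r1 0.08, E24r3 0.0542, E48r1 0.236, E48r3 0.149, V24r1 0.128, V24r3 0.0886 and V48r3 0.391), and that median was -0.201 without V48r3. Without E48r3 the medians were -0.434 for G2/M, 0.0195 for glycolysis and 0.114 for BMP and TGF-beta targets, and that of glycolysis was 0.0503 without E24r1 and 0.131 without E48r2.

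Ribosomal protein transcripts had a lower response at 48 h than at 24 h in 45 of 72 cases by the test of the difference (adjusted p = 0.235 with an estimated correlation), and the members below 0 numbered 72 with TMM, 70 with RLE, 71 with library size only and 68 with mitochondrially encoded genes removed. Both libraries high in mitochondrial transcripts are argued against as the cause by a median of -0.217 without them. So is scaling, the median nearest 0 among 4 others being -0.18. A change of isoform length between libraries is argued against by the median of -0.207 with effective-length offsets, and across all tested genes, which are not independent, the difference had a Spearman correlation of -0.0241 with effective length. Short and abundant genes as a class stay open: 76 other genes sought by effective length and CPM had a median of -0.113, and the lowest of 10000 lists drawn from them had -0.195, but their effective length (604 against 451 bases) did not match. A slower growth that differs between times under the drug may also contribute and was not tested.

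Cholesterol synthesis transcripts rose at 24 h in 20 of 24 cases (adjusted p = 0.101 with an estimated correlation), and 16 had a lower response at 48 h than at 24 h (adjusted p = 0.0551 with an estimated correlation). A single library is argued against by the median nearest 0 without each in turn, -0.229, and transcript length by -0.268 with effective-length offsets. The 4 other scalings (-0.24 nearest 0) again moved all genes too little to decide. A biological change between 24 h and 48 h of treatment remains as a hypothesis, and it could lie in the drug's effect or in the state of the medium and the density of the cells, which the design does not separate.

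The PORCN transcript rose under a drug that inhibits its protein. Reads from the tested neighbouring genes are argued against, since their largest change at 48 h within 20 kb was 0.3421 (TBC1D25). PORCN-DT and Metazoa_SRP also lie within 20 kb and were not tested. Transcript length is argued against by a change of 1.255 with effective-length offsets. The 4 other scalings (lowest change 1.177) moved the median of all genes by at most 0.0532, too little to decide. Whether synthesis or stability raised PORCN was not tested and cannot be decided here.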

How the results depend on the processing

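The omission of V48r3 and E48r2 together and the removal of mitochondrially encoded genes were chosen after the data were seen. Of 14002 values for named genes under the alternatives, 13384 stayed on the same side of the threshold, 497 lost and 118 gained significance, and 3 reversed. A value counted as reversed only where it or the main value was called. Uncalled values that changed direction are therefore among those that stayed. Of 2344 values for lists, 2193 stayed on the same side, 106 lost and 45 gained significance, and 0 reversed in the test's direction by this rule. The median, which can differ in sign from the test, changed sign in 84 of these, 3 of them in a called list, the basal-like list for the difference. The 3 reversals were NKD1 over time in vehicle, with -0.158 and -0.264 for limma on log2(TPM + 1) and log2(TPM + 0.1) and -0.266 with effective-length offsets, against 0.43; the cause was not tested. The number of genes whose response differed was 288 and 265 with limma on log2(TPM + 1) and log2(TPM + 0.1), 404 with effective-length offsets and 709 without V48r3 and E48r2, of which 254, 244, 367 and 628 were among the 1076; apart from fewer samples in the last, the cause was not tested. For vehicle over time limma gave 3247 and 3230, and the cause was not tested. A minimum fold of 1.2 by glmTreat, which asks for larger changes, left 2936 genes at 24 h, 3996 at 48 h, 48 for the difference, 889 for vehicle and 2324 called at both times in the same direction, against 5693. With an estimated correlation camera called 4, 4, 0 and 0 lists (11, 10, 5 and 2 at an unadjusted p under 0.05), and fry, which does not compare a list with other genes, called 5 for the difference and 21 for vehicle. Leaving out 1 library gave 6322 to 7323 genes at 24 h, 7436 to 8110 at 48 h, 517 (without V48r2) to 1433 (without E48r1) for the difference, 4175 to 5772 for vehicle and 5172 to 5624 called at both times in the same direction, with 16 to 18, 16 to 18, 8 to 12 and 11 to 13 lists. The simulation, with fewer genes changed, recovered 6% of 1.2-fold changes for the difference.

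Replicate numbers did not pair the samples: 0 of 18 same-number correlations of deviations from the group means were above 0.1 (-0.11 to 0.0912), and 2 of 18 same-number pairs were the best match. With the number as a replicate block 7045 genes were called at 24 h, 8065 at 48 h, 984 for the difference, 5346 for vehicle and 5635 at both times in the same direction, and 17, 18, 9 and 13 lists. Under it the mitochondrially encoded list was no longer called for the difference (adjusted p = 0.0532), the interferon list was called at 48 h (adjusted p = 0.0227), and among named genes 4 calls ended and 6 were gained. With the replicate block within each time the counts were 6756, 7823 and 758, and for named genes 7 calls ended and 2 were gained.

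Calls of named genes that ended elsewhere included, at 24 h, HES2 (DESeq2 0.0541), PSG1 (effective-length offsets 0.0874), MUC5B (TPM + 1, 0.097) and NOTCH3 (offsets 0.159), and at 48 h IL1RL1 (offsets 0.0944) and KRT6A (without V48r3 and E48r2, 0.229), as adjusted p; the cause was not tested. Without 1 library, calls ended at 24 h for ALDH1L2 (E24r1 0.0535, E24r3 0.0767 and V24r1 0.0869), HES2 (E24r1 0.161, V24r1 0.0822 and V24r2 0.0809), KRT6A (E24r2 0.0624 and V24r2 0.0622) and PSG1 (E24r3 0.123, V24r1 0.061 and V24r2 0.0587), and at 48 h for TMEM160 (E24r2 0.0524, E48r2 0.133, E48r3 0.0848, V48r1 0.0826, V48r2 0.118 and V48r3 0.0516) and KRT6A (E48r2 0.0956, V48r1 0.0594 and V48r3 0.0654).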

Other observations

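The gene families here, defined by their symbols, and all other tests of this part were chosen after the data were seen, and the family definitions were narrowed after a first look. Tests were run on 14 families, with p adjusted over these. Of 17 tested integrin genes 14 rose and 0 fell by edgeR at 24 h (median 0.43, camera adjusted p = 5.8e-08, adjusted p = 0.0141 with an estimated correlation), and 15 rose at 48 h (median 0.592, camera adjusted p = 4.5e-10, adjusted p = 0.00415 with an estimated correlation). ITGB4, an integrin chain of hemidesmosomes, changed by 0.61 ± 0.04 and 0.92 ± 0.04, and the fibronectin receptor chain ITGA5 by 0.77 ± 0.07 and 1.08 ± 0.07. Laminin chains rose in 6 of 9 cases at 24 h and 8 of 9 at 48 h (medians 0.455 and 0.633, camera adjusted p = 5.5e-07 and 1.1e-07, adjusted p = 0.0919 and 0.0958 with an estimated correlation). Keratins rose in 9 and fell in 1 of 13 at 24 h and in 8 and 1 at 48 h (medians 0.485 and 0.312, camera adjusted p = 1.1e-04 and 1.3e-04, adjusted p = 0.0871 and 0.0958 with an estimated correlation). S100 genes, which encode small calcium-binding proteins, rose in 10 of 10 at 24 h and 7 of 10 at 48 h (medians 0.394 and 0.287, camera adjusted p = 0.00144 and 0.0286, adjusted p = 0.204 and 0.286 with an estimated correlation). Claudins, which form tight junctions, rose in 7 and fell in 3 of 13 at 24 h and in 9 and 3 at 48 h (medians 0.324 and 0.452, camera adjusted p = 0.134 and 0.0342, adjusted p = 0.355 and 0.208 with an estimated correlation).

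Nucleoporin genes fell in 20 of 21 cases at 24 h and in 21 of 21 at 48 h (medians -0.434 and -0.455, camera adjusted p = 3.0e-11 and 2.9e-09, adjusted p = 0.0871 and 0.119 with an estimated correlation). All 8 genes of the cytosolic chaperonin fell at both times (medians -0.325 and -0.421, camera adjusted p = 1.9e-05 and 5.6e-06, adjusted p = 0.204 and 0.173 with an estimated correlation). Mitochondrial ribosomal protein genes fell in 56 and rose in 2 of 78 at 24 h and in 59 and 4 at 48 h (medians -0.224 and -0.312, camera adjusted p = 1.0e-07 and 4.5e-08, adjusted p = 0.204 and 0.173 with an estimated correlation). Cytosolic tRNA synthetase genes fell in 10 and 13 of 17 (medians -0.167 and -0.259, camera adjusted p = 0.0115 and 2.7e-04, adjusted p = 0.316 and 0.173 with an estimated correlation), and kinesins fell in 13 and 16 and rose in 5 and 5 of 28 (medians -0.251 and -0.233, camera adjusted p = 9.4e-04 and 7.6e-05, adjusted p = 0.205 and 0.173 with an estimated correlation). Proteasome genes rose in 2 and fell in 5 of 37 at 24 h and in 1 and 25 at 48 h (medians -0.011 and -0.123, camera adjusted p = 0.613 and 0.0107, adjusted p = 0.482 with an estimated correlation at 48 h). The vacuolar ATPase, with 8 higher and 3 lower of 17 at 24 h and 9 and 2 at 48 h, and the ZNF-named zinc finger genes, with 31 and 75 of 399 and 44 and 110, were not called as families (camera adjusted p = 0.216 and 0.145, and 0.134 and 0.0845). Called for the difference between the times were proteasome genes (4 lower, median -0.136, camera adjusted p = 1.3e-05), integrins (3 higher, 0.0637, 0.00397), tRNA synthetases (3 lower, -0.126, 0.00843), kinesins (1 higher and 4 lower, -0.133, 0.0165), none with an estimated correlation (adjusted p = 0.54, 0.12, 0.54 and 0.54), and tubulins. Of 9 tubulin genes 4 fell at 24 h (median -0.172, camera adjusted p = 0.0368, adjusted p = 0.397 with an estimated correlation), and 4 had a higher response at 48 h (median difference 0.286, camera adjusted p = 7.7e-12, adjusted p = 0.12 with an estimated correlation), among them TUBB3, which encodes a tubulin chain known from neurons (-0.62 ± 0.05 at 24 h and 0.46 ± 0.05 at 48 h). Scaling moved the median of all genes by up to 0.0658.

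A hypothesis was that the change with time in vehicle goes in the same direction as the response to ETC-159, beyond what the vehicle libraries they share produce. Over 14808 genes the covariance of log2 fold changes was 0.063 between the 24 h response and the vehicle time course, against 0.0181 (0.0151 to 0.0204) in 20 simulations with no effect. For the 48 h response it was 0.0203, against -0.0186 (-0.0222 to -0.0165). The excess was 0.0449 and 0.0389, which is consistent with a shared direction, and Pearson's r across genes, which are not independent replicates, was 0.422 and 0.118 (simulated 0.487 and -0.496). With 3 vehicle libraries per time the controls cannot be divided with 2 in each part, and the excess was not checked on separate controls.

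The gene length weighted by isoform abundance was tested with limma on the log2 scale in 10287 genes with a mean count of at least 100. At 24 h 0 genes were called (550 at an unadjusted p under 0.05) and at 48 h 3 (922 unadjusted). Of these 3, the genes with a change of at least 10%, chosen after their values were seen, were SRCAP, a chromatin remodelling enzyme whose mean length was 6716 bases in vehicle and 5670 in ETC-159, and TMEM167A, with 1806 and 2108 bases (adjusted p = 0.0221 for each).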
